A study of Mus musculus with 10 samples.

How the data were processed

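RNA-seq was carried out on germinal vesicle oocytes of 10 mice, 1 pool of 16 oocytes per mouse. Per the labels' protocols, oocytes were isolated in medium with milrinone, which blocks the phosphodiesterase that would let meiosis resume. RNA was extracted with an RNeasy Micro kit, cDNA was amplified by single-primer isothermal amplification (NuGen Ovation RNA-Seq) and libraries were made with a TruSeq DNA kit, which does not mark strand. Amplification from small pools adds spread between libraries, and its dependence on transcript length and GC content can shift a gene's value.

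The deposited values are RPKM, reads scaled to transcript length and library total, in 1 table of 34768 RefSeq transcripts and 24453 gene symbols with 1 column per library. The submitters' processing notes name bcl2fastq 1.8.3, STAR and the genome build mm10. The counting tool and its treatment of reads that match several places are not given in the sources used here. If such reads were dropped, genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, are listed below their true level. Where several rows carried a symbol, the row with the highest mean RPKM stood for the gene.

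Because RPKM are not counts, tests were run on log2(RPKM + 0.5), and changes on this scale understate those of low genes. Genes with a mean of at least 0.5 RPKM over the 10 libraries were tested (11338). The linear models of limma 3.58.1 in R 4.3.3 with an empirical Bayes trend were used, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The main model had 2 levels, mutant and control, because the study's design names both control genotypes together. The comparisons with each control group, and between the control groups, came from a model with 3 groups that share 1 estimate of the spread. Setdb1 was tested alone, with an exact two-sided permutation test. All adjusted p-values of genes in the text are from limma.

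Gene lists were tested with camera in limma with a preset correlation between genes of 0.01, for the 19 of 22 lists with at least 5 tested members, and again with an estimated correlation. The lists cover H3K9 methylation and heterochromatin, DNA methylation and TET enzymes, oocyte-specific genes, cAMP signalling, CDK1 regulation, the spindle, cohesin and the chromosome axis, DNA damage, p53 and p63 targets, the interferon response, piRNA and small RNA genes, germline genes, two-cell-stage genes, imprinted genes, Zfp genes, clustered protocadherins, histones, ribosomal proteins, mitochondrially encoded genes, and markers of granulosa cells, theca and stroma, and blood, immune and endothelial cells.

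The named genes are Setdb1, the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold, and up to 4 members of each list with the smallest p. For the first 2 sets, all 4 mutant values had to lie on one side of all 6 control values and the higher group mean had to be at least 1 RPKM. Setdb1 met this rule and is itself 1 of the 12 decreases. Symbols of predicted genes and small RNAs were counted and not named: 2 lay above the last named increase and 1 beyond the last named decrease. In all, 270 increases and 196 decreases were eligible. Groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

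No read totals are part of the table. Where whole reads are counted, the values of a transcript are multiples of what 1 read is worth. The spacing of low values, with transcript lengths from GENCODE M21 for 97.7% of rows, gave 45.9e6 to 72.7e6 reads per library. With these totals, 62.9% to 65.3% of low values came out within 0.1 of a whole read, so the totals and reads are approximate. In the shallowest library, 10 reads on a transcript of 2 kb correspond to 0.109 RPKM. Values near or below this level rest on few reads, and amplified reads are not independent molecules.

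Each library counted as 1 replicate because it came from a separate mouse. With the recovered reads, the 13 pairs of libraries within a group differed by a chi-square of 23.1 to 263 per gene, which only speaks against 1 library having been sequenced again under another label. The limma model was tested on simulated data for the 11338 genes. For mutant against all controls it recovered 41% of genes changed by 1 on the log2 scale and 86% of those changed by 2, and 11 of 138 calls were unchanged genes. For mutant against f/+; Zp3-cre the recovery was 34% and 80%, for mutant against f/- 20% and 64%, and between the control groups 23% and 64%. The simulation gave a gene the same spread in all libraries. In the data the median SD of a gene on the log2 scale was 0.19 in f/+; Zp3-cre, 0.39 in mutants and 0.39 in f/-. Recovery and wrong calls may therefore differ in the data, above all against the 2 f/- libraries.

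Alternatives covered the pseudocount, the scaling, the filter on low values, the estimate of the spread, library weights, the threshold, the way rows of a symbol are joined, the control libraries, a block for the replicate number and the omission of each library. Gene positions are from RefSeq on GRCm38 (the assembly also called mm10) and exon overlaps from GENCODE M21. Positions on the chromosomes were found for 11319 of the 11338 tested genes. Distances between genes, lists matched on length, and figures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Random gene sets numbered 10000. The test of distances was tried on simulated calls, where random calls gave a permutation p of 0.81 and 30 planted pairs a permutation p of 0.002.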

Results

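RNA was profiled from germinal vesicle oocytes, the full-grown oocytes that are arrested in prophase of the first meiotic division, of 10 C57Bl/6J mice. Each library came from a pool of 16 denuded oocytes of 1 mouse, so replicates are separate animals. Setdb1 encodes a histone methyltransferase that places methyl groups on lysine 9 of histone H3. Oocytes from 4 mice with a floxed and a deleted Setdb1 allele and the Zp3-cre transgene, which is active in growing oocytes, form the mutant group. The series asks what these oocytes need Setdb1 for, in meiosis and in the early embryo, and the libraries cover the stage before meiosis resumes. The controls are 4 mice with a floxed and a wild-type allele plus Zp3-cre (f/+; Zp3-cre) and 2 mice with a floxed and a deleted allele but no Cre (f/-). The values are RPKM of RefSeq transcripts, and the spacing of the low values put the libraries between 45.9e6 and 72.7e6 reads. Values below are means ± SD over 4 mutant and 6 control libraries unless another group is named.

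Setdb1 itself was checked first, in every library. Its RPKM was 4.06, 2.55, 3.32 and 1.31 in mutant replicates 1 to 4. In the f/+; Zp3-cre replicates it was 28.6, 25.7, 25.1 and 52.5, and in the f/- replicates 19.9 and 26.3. The mutant mean of 2.81 ± 1.17 (SD, n = 4) was 9.47% of the control mean of 29.7 ± 11.5 (SD, n = 6), and no mutant library reached any control library. The difference was -3.20 on the log2(RPKM + 0.5) scale, with a two-sided exact permutation p of 0.0048, the smallest that the 210 splits of the libraries allow. The control groups, at 32.9 ± 13.1 (n = 4) and 23.1 ± 4.48 (n = 2), differed by 0.45 on that scale (exact permutation p = 0.47 over 15 splits). Setdb1 lies on chromosome 3 from 95323525 to 95357202 in GRCm38, on the minus strand, and shares exon sequence with Cers2 and Gm37500 on the opposite strand. Which exon is floxed is not given in the sources used here, and the RPKM covers the whole transcript, so it may include parts that were not deleted.

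**Figure D1:**
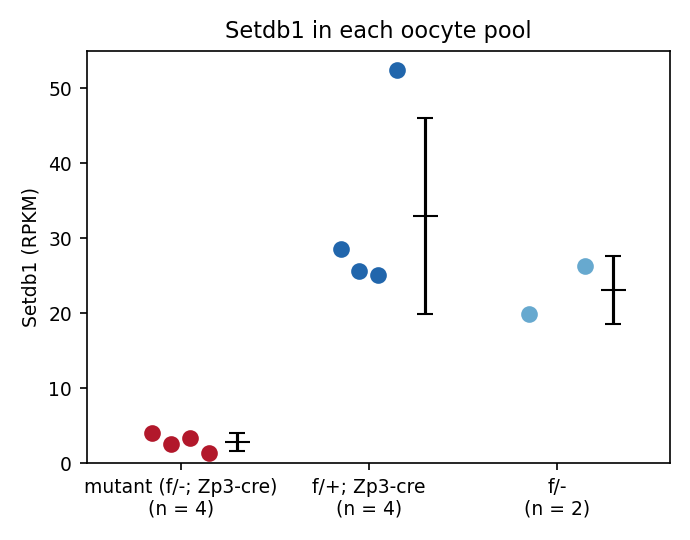
Setdb1 RPKM (vertical axis, linear from 0) in each of the 10 oocyte pools, by genotype (horizontal axis); points are libraries and bars show the mean ± SD of each group. The 4 mutant pools lie between 1.31 and 4.06 RPKM, and the control pools between 19.9 and 52.5.

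The main comparison asks which transcripts differ in oocytes that lose Setdb1 during growth. Genes that were nearly silent in control oocytes were among those that rose most. Lsmem1, which encodes a small membrane protein, stood at 32.0 ± 4.80 RPKM in mutants against 0.571 ± 0.333 in controls (log2 change 4.97 ± 0.28 SE). Hpse, which encodes the enzyme heparanase, rose from 5.53 ± 1.28 to 78.6 ± 15.2 RPKM, and Cyp2c29, a cytochrome P450 gene, from 4.89 ± 1.04 to 74.7 ± 18.8. Among the genes that fell, the transcription factor gene Sox8 went from 15.4 ± 2.80 to 1.85 ± 0.932 RPKM and St3gal5, which encodes the synthase of the ganglioside GM3, from 7.47 ± 1.72 to 0.693 ± 0.319. Of 11338 genes tested with limma, 352 were higher and 252 lower in mutants at the adjusted p threshold, and 2242 had an unadjusted p below 0.05 where 566.9 would by chance.

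The other genes with the largest increases covered several functions. Bglap3, related to osteocalcin, rose from 0.227 ± 0.345 to 18.9 ± 6.02 RPKM. Ifi27l2a, a member of a family of interferon-inducible genes, was listed at 0 in both f/- libraries and at a mean of 0.025 ± 0.0313 in f/+; Zp3-cre, and stood at 13.8 ± 4.91 in mutants. The MADS-box factor Mef2b rose from 2.06 ± 0.685 to 47.2 ± 6.10 RPKM, and the amino acid transporter gene Slc38a1 from 0.403 ± 0.257 to 12.2 ± 0.480. Stox1 reached 9.22 ± 2.71 RPKM, Olfr1197, an olfactory receptor gene, 7.34 ± 1.69, Adam5, which belongs to a family of membrane metalloproteases, 6.89 ± 1.75, Tulp2 6.37 ± 3.17 and Clrn3 5.15 ± 2.09. Each of these 5 was below 0.4 RPKM on average in controls. The limma adjusted p of the 12 named increases lay between 1.1e-07 and 7.0e-05, and all 4 mutant libraries lay above all 6 control libraries for each.

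Several other genes fell, all but Inadl to a mutant mean below 0.5 RPKM. Inadl, a cell polarity gene now called Patj, fell from 12.3 ± 1.77 to 1.54 ± 0.756 RPKM, and Ust, which encodes a sulfotransferase, from 5.29 ± 2.83 to 0.373 ± 0.275. Cdc42ep3 fell from 4.56 ± 1.04 to 0.476 ± 0.441 RPKM, Trim35 from 3.91 ± 2.00 to 0.0578 ± 0.0566, and Fam83d, whose product binds the spindle, from 3.78 ± 1.67 to 0.129 ± 0.104. Ntm, Tnfrsf21 and Tuba3b fell to 0.219 ± 0.159, 0.116 ± 0.171 and 0.0468 ± 0.0299 RPKM, from 3.82 ± 4.33, 3.01 ± 1.45 and 2.57 ± 1.5. Ntm had 12.6 RPKM in f/- replicate 1 and 1.13 to 2.81 in the other controls. Actg2, a smooth muscle actin gene, went from 5.18 ± 8.23 to 0.0799 ± 0.0813 RPKM. Actg2 had 21.9 RPKM in f/- replicate 2 and 0.629 to 3.34 in the other controls. Its limma adjusted p of 0.036 was lost on leaving out any mutant replicate or f/+; Zp3-cre replicate 1, 2 or 4 (0.051 to 0.088).

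**Figure D2:**
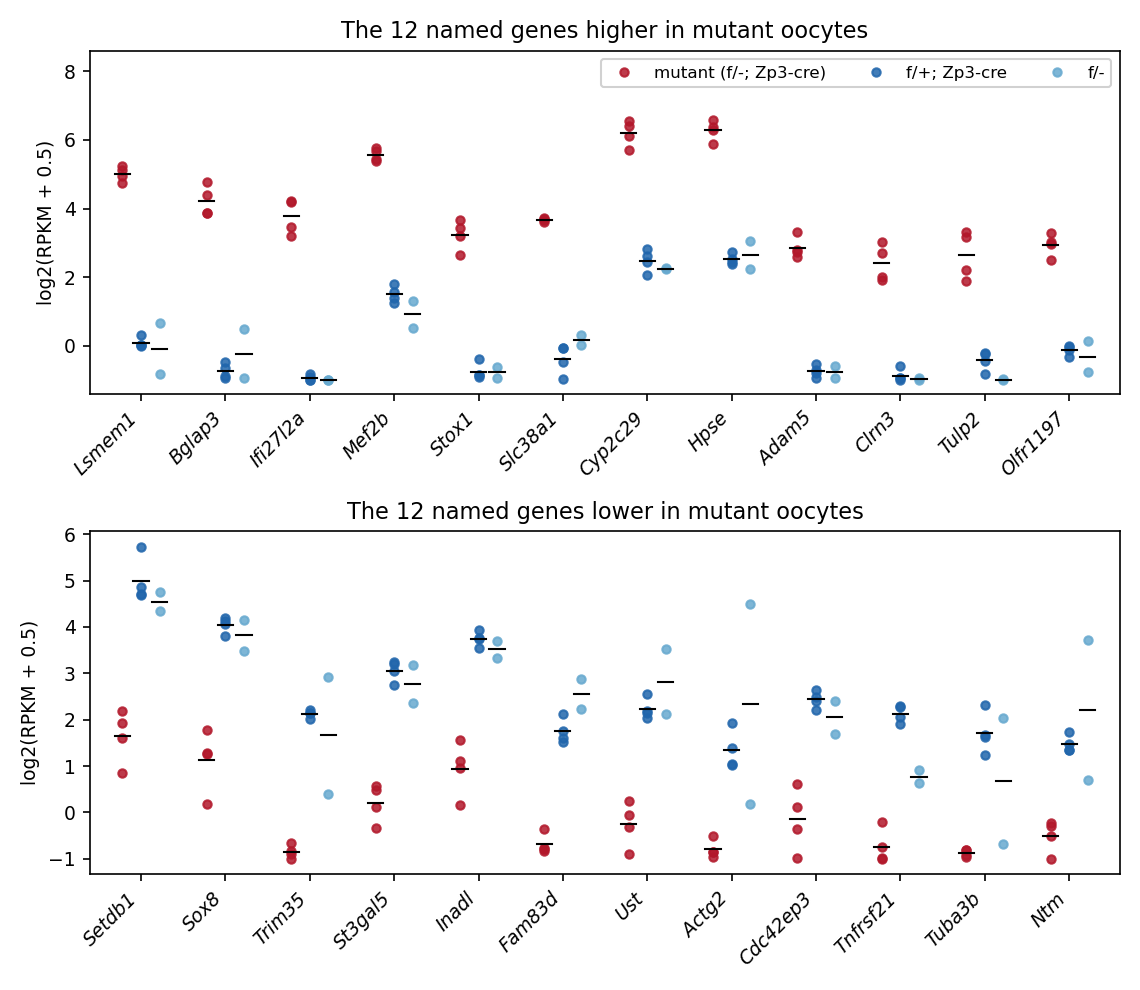
Values on the log2(RPKM + 0.5) scale (vertical axes) of the 12 genes with the largest increases (top) and the 12 with the largest decreases, Setdb1 included (bottom). Points are libraries, coloured by genotype, and short lines are group means. For every gene shown, all 4 mutant libraries lie on one side of all 6 control libraries, and in Lsmem1 the mutants average 32.0 RPKM against 0.571 in controls.

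The median control level was 4.81 RPKM for the 352 higher genes, 8.14 for the 252 lower genes and 5.94 for all tested genes. Below 1 RPKM in controls were 89 of the higher genes (25.3%), 5 of the lower genes (1.98%) and 12.8% of all tested genes. The filter and the added 0.5 RPKM favour increases among such low genes, so these shares do not compare the directions. The change was at least 1 on the log2 scale in 227 higher and 154 lower genes, and at least 2 in 72 and 23. In 928 tested genes (8.18%, against 0.952% by chance) all mutant libraries lay on one side of all controls, including 301 of the higher and 212 of the lower genes. The split between directions moved with the scaling of the libraries: 58.3% of calls were increases in the values as deposited, 47.7% after median centring (306 higher, 336 lower) and 48.9% after quantile normalization (322 higher, 337 lower). Array weights, which lower the influence of variable libraries, raised the counts to 807 and 581. Without mutant replicate 1 or 4 the lower genes numbered 167 and 164, and without f/+; Zp3-cre replicates 1 to 4 they numbered 127, 121, 159 and 140.

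Some of the named genes share sequence or position with others, and the library kit did not mark strand. Mef2b (chromosome 8, 70152761 to 70167488) overlaps exons of Borcs8 on its own strand, and Cyp2c29 (chromosome 19, 39287044 to 39330713) those of Cyp2c53-ps. Tulp2 (chromosome 7, 45482026 to 45523646) overlaps exons of Dhdh and Ppp1r15a on the opposite strand. Sox8, Trim35, Lsmem1 and Cdc42ep3 overlap exons of transcripts annotated on the opposite strand. The values of the partners were not compared for this question, so the increases or decreases of these genes are not assigned to 1 partner. Hpse (chromosome 5, 100679484 to 100719716), Slc38a1 (chromosome 15, 96571418 to 96643438) and St3gal5 (chromosome 6, 72097552 to 72154571) overlap no other annotated exon.

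**Figure D3:**
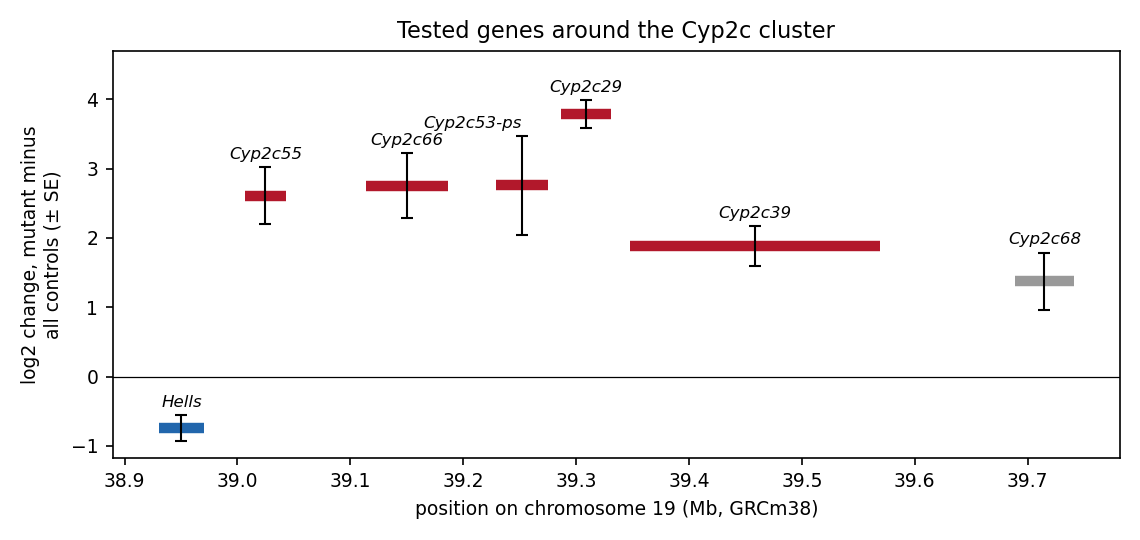
Log2 change of mutants minus all controls on the log2(RPKM + 0.5) scale (vertical axis, error bars are SE) of the tested genes around the Cyp2c cluster against their position on chromosome 19 (horizontal axis, Mb in GRCm38); red marks higher, blue lower and grey genes that did not pass. Cyp2c29 has the largest change, at 3.79, and Hells lies on the other side of 0, at -0.74.

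Among 22 gene lists fixed beforehand, 3 passed with the preset correlation between genes: the cytosolic ribosomal protein and histone genes towards higher and the oocyte-specific genes towards lower values in mutants. None passed with an estimated correlation (adjusted p = 0.39, 0.39 and 0.46 with an estimated correlation). Of 70 ribosomal protein genes tested, 4 rose, none fell and 66 did not pass, and the list's mean log2 change was 0.35, or 0.20 with a trend in transcript length and GC content removed. Against f/- alone none of the 70 rose and 1 fell by limma (2434 of all genes had an unadjusted p below 0.05), and the list mean was 2.86 and 2.42 in the f/- replicates, 2.87 to 2.96 in mutants and 2.47 to 2.70 in f/+; Zp3-cre. Rpl32 rose from 56.5 ± 8.54 to 83.5 ± 5.94 RPKM, Rps15 from 28.8 ± 9.04 to 50.3 ± 4.32, Rps26 from 25.4 ± 3.73 to 40.3 ± 7.4 and Rpl39l from 21.5 ± 8.18 to 39.5 ± 3.57. Of 24 histone genes, 5 rose and none fell (7 adjusted over the list alone), with a mean log2 change of 0.66. That mean was 0.26 with no filter on low values, where the camera adjusted p was 0.048 with the preset correlation. It was 0.43 with a pseudocount of 2 and 0.85 with a pseudocount of 0.1. The linker histone gene Hist1h1a rose from 48.7 ± 3.51 to 84.9 ± 12 RPKM, Hist1h2aa from 129 ± 38.0 to 269 ± 30.7, Hist1h4c from 3.05 ± 1.31 to 7.52 ± 1.66 and Hist1h1d from 0.292 ± 0.247 to 1.68 ± 0.482. The camera adjusted p with the preset correlation was 1.1e-06 for the ribosomal protein list and 0.00015 for the histone list. It was 0.39 for each with an estimated correlation. The mean of the histone list in the f/- libraries, at 2.04 ± 0.30 (n = 2) on the log2 scale, lay nearer the mutant mean of 2.28 ± 0.14 (n = 4) than the f/+; Zp3-cre mean of 1.42 ± 0.13 (n = 4). Against f/+; Zp3-cre alone the histone list passed both ways, with a camera adjusted p of 2.3e-07 and an adjusted p = 0.040 with an estimated correlation.

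Of 32 oocyte-specific genes, 3 fell, 1 rose and 28 did not pass (4 lower and 1 higher adjusted over the list alone). Kit, the receptor for Kit ligand, fell from 69.9 ± 5.03 to 40 ± 6.76 RPKM. Nlrp9b fell from 214 ± 31.6 to 126 ± 5.83 RPKM and Nlrp14 from 652 ± 73.5 to 464 ± 52.3, whereas Nobox, a homeobox factor of oocyte growth, rose from 205 ± 21.3 to 274 ± 25.5. The list's camera adjusted p was 0.0052 with a mean log2 change of -0.15. It was 0.46 with an estimated correlation, 0.16 with array weights and 0.070 with f/+; Zp3-cre as the only controls.

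**Figure D4:**
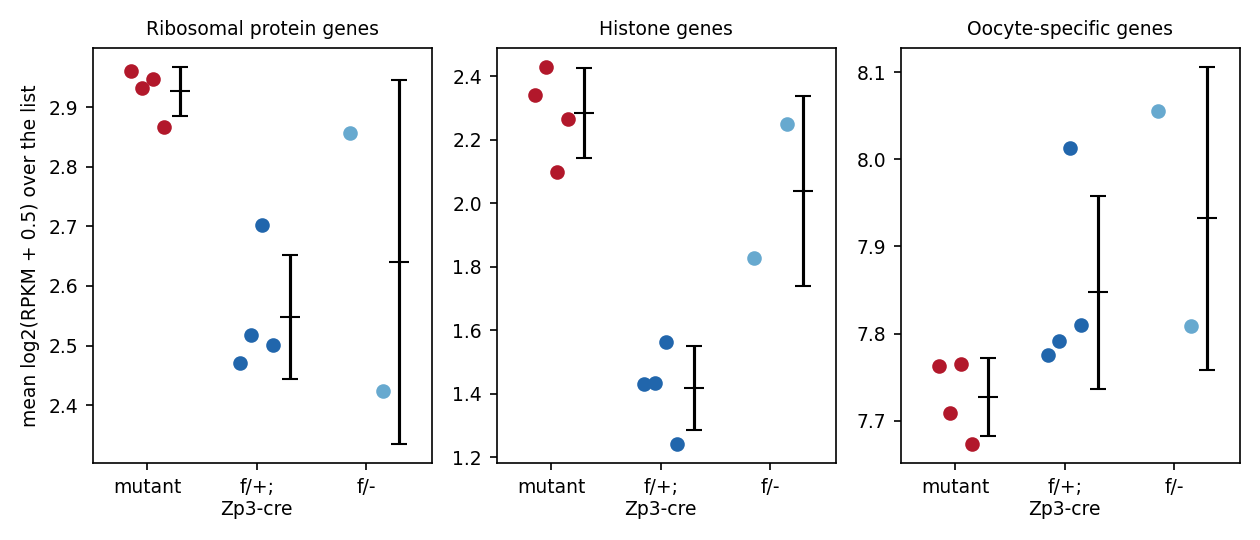
Mean log2(RPKM + 0.5) over the tested genes of 3 lists (vertical axes, which do not start at 0) in each library by genotype; points are libraries and bars show the mean ± SD of each group. The histone list averages 2.28 in mutants, 1.42 in f/+; Zp3-cre and 2.04 in f/-.

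Single members of the lists on chromatin and DNA methylation changed. Of the 33 list members past the threshold that were followed one by one, at most 4 per list, 10 passed at the same threshold in all alternative settings in which single genes were followed, 26 for most genes. Dnmt1 is among them, and Hells was lost in 11 of 26. Dnmt1, the maintenance DNA methyltransferase, fell from 514 ± 32.7 to 351 ± 22.8 RPKM (limma adjusted p = 0.00081) and was the only 1 of 14 DNA methylation and TET genes to pass. Hells, a chromatin remodeller, fell from 18.3 ± 3.6 to 10.6 ± 1.37 RPKM (limma adjusted p = 0.031) and was the only 1 of 24 H3K9 methylation and heterochromatin genes to pass over all genes; adjusted over the list alone, 2 were higher and 1 lower. Of 238 tested Zfp genes, most of which encode zinc finger factors, 9 rose and 2 fell. Zfp58 rose from 34.7 ± 2.74 to 105 ± 22.2 RPKM, Zfp763 from 0.565 ± 0.385 to 8.35 ± 2.91 and Zfp641 from 0.127 ± 0.0767 to 4.32 ± 2.59, whereas Zfp41 fell from 3.0 ± 0.554 to 0.425 ± 0.339. The camera adjusted p of these 3 lists was 0.62, 0.51 and 0.34, and the Zfp list passed towards higher values among genes of at least 2 RPKM (0.049 with the preset correlation). Over all its tested genes its adjusted p = 0.49 with an estimated correlation.

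Single genes of the meiotic lists passed, in counts to be read beside 604 of all 11338 tested genes. Of 25 genes of cAMP and protein kinase A signalling, which holds oocytes in prophase, Pde8a fell from 8.75 ± 1.48 to 4.03 ± 0.718 RPKM and Gnai1 from 17.1 ± 4.23 to 8.66 ± 2.95, and none rose (2 higher and 3 lower adjusted over the list alone). None of 31 CDK1 regulators passed, by limma over all genes or adjusted over the list alone. Wee1, the kinase that inhibits CDK1, had 11 ± 2.69 RPKM in mutants and 6.36 ± 1.26 in controls, with a limma adjusted p of 0.055. Of 35 spindle and kinetochore genes, Spc24 rose from 8.15 ± 2.04 to 14.7 ± 3.77 RPKM (none adjusted over the list alone). Of 31 cohesin and chromosome axis genes, Sycp1, a component of the synaptonemal complex, rose from 1.34 ± 0.267 to 3.6 ± 1.03 RPKM, Top2a fell from 17.5 ± 1.35 to 11.6 ± 1.27 and Syce1 fell from 1.22 ± 0.887 to 0.120 ± 0.124. Of 33 DNA damage genes, Trp53bp1 fell from 12.8 ± 0.581 to 8.01 ± 1.19 RPKM and H2afx rose from 102 ± 22.6 to 150 ± 17.4 (1 higher and 3 lower adjusted over the list alone). The camera adjusted p of these 5 lists lay between 0.12 and 0.92, and the DNA damage list passed towards lower values with quantile normalization (0.041 with the preset correlation). For mutants against all controls without that step its adjusted p = 0.39 with an estimated correlation.

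Calls among germline, imprinted and early embryonic genes are likewise to be read beside 604 of all 11338 tested genes. Of 22 germline genes that are silenced in somatic cells, Dazl fell from 92.4 ± 3.43 to 65.3 ± 14.0 RPKM and Stk31 from 10.8 ± 1.90 to 5.88 ± 1.61, beside the fall of Tuba3b and the rise of Sycp1 (4 lower and 1 higher adjusted over the list alone). Gtsf1 fell from 152 ± 17.2 to 98.4 ± 16.9 RPKM as the only 1 of 20 piRNA and small RNA genes (2 lower adjusted over the list alone). Of 22 imprinted genes, Igf2 fell from 2.16 ± 1.89 to 0.126 ± 0.115 RPKM, Usp29 fell from 5.46 ± 0.753 to 2.49 ± 0.964 and Dio3 rose from 0.164 ± 0.142 to 1.02 ± 0.113. Of 8 genes linked to the two-cell stage and MERVL elements, Arg2 rose from 85.7 ± 22.9 to 133 ± 7.92 RPKM. None of 10 p53 and p63 targets and none of 8 interferon response genes passed over all genes by limma, and 1 interferon gene was lower adjusted over the list alone. Over these 6 lists the camera adjusted p lay between 0.13 and 0.62. The two-cell-stage list passed towards higher values with f/+; Zp3-cre as the only controls (camera adjusted p = 0.023), with array weights (0.020) and without f/- replicate 1 (0.032), each with the preset correlation. In mutants against all controls its adjusted p = 0.39 with an estimated correlation.

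None of the tested markers of other ovarian cells passed by limma, and their levels varied widely. Of the 7 tested granulosa and cumulus markers, Serpine2 had 65.0 ± 9.81 RPKM in mutants and 66.0 ± 11.7 in controls, Nr5a2 13.2 ± 5.0 and 12.7 ± 2.04, and Cyp19a1 8.22 ± 2.14 and 6.57 ± 1.78. Lower were Inha at 1.56 ± 0.880 RPKM in mutants and 0.804 ± 0.646 in controls, and Ptgs2 at 1.74 ± 0.626 and 0.770 ± 0.529. Kitl was at 0.542 ± 0.399 RPKM in mutants and 0.885 ± 0.346 in controls, and Fshr at 0.733 ± 0.596 and 0.667 ± 0.358. Among 5 tested markers of blood, immune and endothelial cells, Pecam1 had 13.7 ± 5.23 RPKM in mutants and 20.1 ± 4.35 in controls, and C1qb 12.7 ± 2.11 and 14.5 ± 3.54. Kdr had 1.15 ± 0.907 RPKM in mutants and 0.353 ± 0.162 in controls, and Tie1 0.874 ± 0.278 and 1.54 ± 0.785. The 1 tested theca and stroma marker, Hsd3b1, had 1.79 ± 1.06 RPKM in mutants and 1.36 ± 0.996 in controls. The camera adjusted p was 0.62 for the granulosa list and 0.62 for the blood list. The theca list and the 2 tested clustered protocadherin genes were too few for the list test, neither protocadherin gene passed by limma, and the table holds no mitochondrially encoded gene. Median, mean and test differed in sign for the CDK1, interferon and blood lists.

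Against f/+; Zp3-cre alone, which also carries Cre, 313 genes were higher and 241 lower in mutants in the model with 3 groups. All 12 of the named increases and 11 of the 12 named decreases passed in this comparison, which their selection against all controls, these libraries included, largely fixed. The decreases that passed include Setdb1, the deleted gene. Lsmem1 stood at 0.570 ± 0.122 RPKM in f/+; Zp3-cre (n = 4) and Hpse at 5.29 ± 0.584, against the mutant values above. Dnmt1 was at 510 ± 39.5 RPKM, and its change of -0.54 ± 0.08 (SE) passed (limma adjusted p = 0.0022). Actg2, at 2.14 ± 0.840 RPKM, did not pass (limma adjusted p = 0.10). Among the named list members past the threshold against all controls, Igf2, Dio3, Arg2 and Rpl39l did not pass (limma adjusted p = 0.060, 0.056, 0.051 and 0.095). Igf2, Arg2 and Rpl39l did not pass against f/- alone either (limma adjusted p = 0.053, 0.13 and 0.099). The count of 554 changed genes rose to 1396 with array weights, and without single f/+; Zp3-cre replicates 1 to 4 it was 257, 226, 355 and 248. Without f/- replicate 1 it was 904, and without f/- replicate 2 it was 905.

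Against f/- alone, which has the mutants' Setdb1 alleles without Cre, 369 genes were higher and 180 lower in mutants. The estimate of the spread is shared with f/+; Zp3-cre, whose median SD of a gene was 0.19 on the log2 scale. That SD was 0.39 in mutants and 0.39 in f/-, so the p-values of this comparison may be too small. All 12 named increases passed here as well, which the selection likewise favoured, with Mef2b at 1.47 ± 0.746 RPKM and Cyp2c29 at 4.27 ± 0.0563 in f/- (n = 2). Of the named decreases 10 of 12 passed, with Setdb1 itself counted among them. Tuba3b, at 1.87 ± 2.48 RPKM in f/-, and Actg2, at 11.3 ± 15, did not (limma adjusted p = 0.16 and 0.053). Dnmt1 was at 523 ± 20.7 RPKM in f/-, and its change of -0.58 ± 0.10 (SE) passed (limma adjusted p = 0.0065). Kit, Nlrp9b, Dio3, Zfp58, Zfp763, Zfp641, Zfp41, Hist1h1a, Hist1h2aa and Hist1h1d passed as well. The other named list members past the threshold against all controls kept their direction but did not pass against the 2 f/- libraries. Among them were H2afx, Syce1, Gnai1, Spc24, Hells and Nobox (limma adjusted p = 0.34, 0.29, 0.22, 0.21, 0.21 and 0.18). Array weights were 0.39 and 0.24 for the f/- replicates and 0.95 to 4.87 for the f/+; Zp3-cre replicates. With these weights the count of changed genes was 52, against 549. It was 283, 277 and 291 without f/+; Zp3-cre replicate 1, 2 or 4, and 1467 without f/- replicate 1.

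The control groups differed in 8 genes, with 3 higher and 5 lower in f/+; Zp3-cre than in f/-. The metallothionein gene Mt1 was at 106 ± 69.4 RPKM in f/+; Zp3-cre (n = 4) and 0.376 ± 0.0781 in f/- (n = 2). Tmem182 was at 6.82 ± 0.951 and 0.886 ± 0.347 RPKM, and Mir6537 at 7.91 ± 1.34 and 0.735 ± 0.200. Higher in f/- were Defb41 (39.5 ± 28.0 against 5.06 ± 1.62 RPKM), Tsacc (41.5 ± 3.97 against 13.6 ± 2.12), Hist2h2bb (9.70 ± 2.04 against 1.43 ± 0.256), Tmod4 (7.11 ± 1.60 against 0.336 ± 0.228) and Rbm38 (470 ± 19.4 against 266 ± 24.5). These 8 genes are named because they are all that passed, after their values were seen. By limma, 1584 genes had an unadjusted p below 0.05 where 566.9 would by chance, and without f/- replicate 1 or 2 the count was 840 or 17. It was 23 and 44 without mutant replicate 2 or 4, and 0, 0 and 3 without f/+; Zp3-cre replicate 1, 2 or 4.

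Libraries of the f/+; Zp3-cre group resembled each other more than those of the other groups. Pearson correlations across genes between its replicates were 0.972 to 0.987, against 0.886 to 0.955 among mutants and 0.878 between the f/- libraries. The median SD of a gene was 0.19 on the log2 scale in f/+; Zp3-cre, 0.39 in mutants and 0.39 in f/-. Symbols with a value above 0 numbered 15947 to 16730 in f/+; Zp3-cre, 13844 to 15469 in mutants, and 14157 and 13723 in f/-. Whether the groups shared litters or library batches is not given in the sources used here. Without 3 libraries with low correlation to the rest (mutant replicates 2 and 4 and f/- replicate 2), 318 genes were higher and 209 lower in mutants, of which 216 and 130 were among the calls from all libraries. By the median correlation with the other libraries, f/- replicate 1, which was kept, was at 0.909 and mutant replicate 4 at 0.910.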

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

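In groups of 4 libraries, a value was picked out when its gap to the nearest other library took up most of the group's range. This was asked of the genes past the threshold named by the rule and of 3 library measures, 120 groups of values in all. It picked out 7, where chance gives about 6, so the set is no larger than chance would give.

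Setdb1 was 52.5 RPKM in f/+; Zp3-cre replicate 4, against 25.1 to 28.6 in the other replicates of that group. The difference between mutants and all controls without that library was -3.02 on the log2 scale, against -3.20 with it. Nlrp14 was 792 RPKM in f/+; Zp3-cre replicate 3 and 611 to 635 in the others. The remaining values are low. Lsmem1 was 0.753 RPKM in f/+; Zp3-cre replicate 4 (others 0.508 to 0.51), Stox1 0.262 in f/+; Zp3-cre replicate 3 (others 0.0387 to 0.0525) and Clrn3 0.162 in f/+; Zp3-cre replicate 1 (others 0 to 0.0227). Among mutants, Fam83d was 0.284 RPKM in replicate 3 (others 0.063 to 0.0906) and Syce1 0.304 in replicate 2 (others 0.0376 to 0.0781).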

How the results depend on the processing

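The analyses without 3 libraries, on recovered reads and with a trend in length and GC content removed were chosen after seeing the data. Setdb1 stayed lower, from -3.39 (pseudocount 0.1) to -2.69 (pseudocount 2) and from -3.38 to -2.94 with 1 library left out. Without the 3 libraries it was -2.80 (exact permutation p = 0.048, the smallest that 21 splits allow). No called gene of mutant against all controls turned direction under any alternative.

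Array weights gave 807 higher and 581 lower genes, 1396 changed against f/+; Zp3-cre, 52 against f/- and 0 between the controls. An adjusted p below 0.01 gave 149, 63, 198, 159 and 0, in the same order, by limma. A change of at least 1 on the log2 scale left 227 higher, 154 lower and 336 against f/+; Zp3-cre, by construction. No filter on low values gave 150 lower, 345 against f/- and 21 between the controls, which also gave 25 with a pseudocount of 0.1, 17 with quantile normalization and 25 with at least 2 RPKM. With f/+; Zp3-cre as the only controls and the f/- libraries left out of the fit, 514 genes were higher and 395 lower. The 313 higher and 241 lower genes against f/+; Zp3-cre came from the model with 3 groups, whose spread includes f/-. The log2 changes are the same in both fits, so these counts differ through the estimate of the spread. With an estimated correlation 0 lists passed in limma camera, against 3, and by the unadjusted camera p the histone list (0.030) and the DNA damage list (0.041) were under 0.05. Apart from the threshold on size and the fit without f/-, the cause was not tested. On recovered reads voom called 300 higher and 185 lower, of which 273 and 156 were main calls.

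With the replicate number as a block 236 genes were higher and 140 lower, 383 changed against f/+; Zp3-cre, 223 against f/- and 1 between the controls. Libraries with the same number did not deviate together (r from -0.046 to 0.031 over 8 pairs), so no pairing by number was detected. The pairs with f/- are not independent, because the deviations of its libraries mirror each other. A litter or batch shared by libraries of the same number is not excluded. For Setdb1, permuting within the blocks gave an exact permutation p of 0.028.

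With 1 library left out, higher genes numbered 238 to 439, lower genes 121 to 355 and lists 3 to 4. Lower genes numbered 167 and 164 without mutant replicate 1 or 4 and 127, 121, 159 and 140 without f/+; Zp3-cre replicates 1 to 4. Without those 4 in turn, 257, 226, 355 and 248 changed against f/+; Zp3-cre, and without f/- replicate 1 or 2, 904 and 905. Against f/-, 283, 277 and 291 changed without f/+; Zp3-cre replicate 1, 2 or 4, and 1467 without f/- replicate 1. Between the controls limma gave 840 and 17 without f/- replicate 1 or 2, 23 and 44 without mutant replicate 2 or 4, and 0, 0 and 3 without f/+; Zp3-cre replicate 1, 2 or 4, against 8 (1584 at an unadjusted p below 0.05). Without an f/- replicate the lone f/- library is assumed to vary like the other groups.

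Of the 23 top named genes besides Setdb1, 18 passed in all alternatives followed for single genes (26 for most, without the stricter threshold and the limit on size). Actg2 was lost in 12 of 26, Ntm in 4, Tuba3b in 2 of 25, and Trim35 and Tnfrsf21 in 1, on recovered reads. Of the 33 list members past the threshold that were followed (at most 4 per list), 10 passed in all of these: Dnmt1, Kit, Nlrp9b, Pde8a, Hist1h1a, Hist1h2aa, Zfp58, Zfp763, Zfp641 and Zfp41. Spc24, Syce1, Rpl39l, H2afx, Hells and Arg2 were lost most often (10 to 15 alternatives). Genes not past the threshold turned sign in 6 cases. Pcdha11 was -0.021 and C1qb 0.057 with array weights. Without the 3 libraries, Pcdha11 was -0.0036, C1qb 0.033, Bst2 0.26 and Kitl 0.0028. Depth limits values near 0.109 RPKM, where 10 reads or fewer decide.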

Other observations

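The tests on the control groups, on granulosa RNA, on the removed trend and on genes near Setdb1 were chosen after the values were seen. The other tests here were set before.

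Of 16 Cyp2c symbols present, 7 were tested, and 5 were higher in mutants and none lower. These cytochrome P450 genes were looked at after Cyp2c29 was seen among the largest increases. The 5 lie next to each other on chromosome 19. From mean RPKM in controls to mutants, Cyp2c55 went from 0.407 ± 0.439 to 4.93 ± 2.37, Cyp2c66 from 0.0453 ± 0.0481 to 4.09 ± 2.48, Cyp2c39 from 0.0761 ± 0.0716 to 1.65 ± 0.528 and the pseudogene Cyp2c53-ps from 27.9 ± 20.6 to 126 ± 38.0. Cyp2c68, at 0.0849 ± 0.0930 and 1.30 ± 1.18 RPKM, and Cyp2c69, at 0.447 ± 0.342 and 0.954 ± 0.808, did not pass (limma adjusted p = 0.073 and 0.49). Hells, which fell, lies beside the cluster, from 38930262 to 38970470.

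The number of genes that changed was not matched by other groupings of the libraries. Of 100 of the 210 splits of the 10 libraries into 4 and 6, 1 (the real one) gave as many as 352 higher genes and 1 as many as 252 lower genes, and the highest of the others gave 0 and 1. Of the 35 splits of the mutant and f/+; Zp3-cre libraries, 1 gave 554 changed genes and the highest of the others 0. Chance alone is thus an unlikely source of these 3 counts, but 100 and 35 splits limit how small a p can be. Other splits put mutants on both sides, which widens their spread and lowers their counts. Litters or library batches that go with genotype are not addressed by such splits. For the 3 gene lists past the threshold chance is left open: 9 of 100 splits gave as many, and the highest of the others gave 5.

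The hypothesis that genes higher in mutants sit near each other was tested by counting pairs within 100 kb. There were 31 such pairs among 351 higher genes with a position, against a mean of 18.1 in random sets matched on expression (permutation p = 0.0058 over 10000 sets). Without pairs that overlap or share a symbol stem, such as the Cyp2c and histone genes, 18 pairs remained against 16.5 in random sets (permutation p = 0.385). Gene families or shared reads may therefore account for the excess, and no excess was detected without them. Genes lower in mutants formed 16 pairs, against 9.26 in random sets (permutation p = 0.0338), and 8 against 8.38 without such pairs (permutation p = 0.589).

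The rise of the ribosomal protein and histone lists was weighed against 4 explanations. A trend with transcript length and GC content does not account for all of it with the preset correlation, since after its removal the larger adjusted camera p of the lists was 0.000811 (before removal, adjusted p = 0.39 for each with an estimated correlation), with mean changes of 0.20 and 0.53 against 0.35 and 0.66 before. The median change of each list was above that of nearly all random lists of matched length and level (percentiles of at least 99.99). Those lists were drawn gene by gene and leave out the correlation between list members. That correlation was estimated at 0.14 for ribosomal protein and 0.10 for histone genes, so the percentiles overstate the evidence. Against granulosa RNA, 19 markers below 1 RPKM in controls differed by a median of 0.00286 RPKM, while ribosomal protein genes differed by 4.02 on average. Markers at 0 RPKM in both groups, such as Krt18 and Ptx3, hold that median near 0. This measure is the third tried and was settled after the values were seen. The 2 before it, on the range of the marker changes and on the largest marker difference (0.972 RPKM, Ptgs2), could not tell. Granulosa RNA is therefore not excluded. A level shared with the f/- controls may account for the histone list, whose adjusted camera p was 0.355 in mutant against f/-, 2.3e-07 in mutant against f/+; Zp3-cre (adjusted p = 0.040 with an estimated correlation) and 0.00034 between the control groups (adjusted p = 0.16 with an estimated correlation). For the ribosomal protein list, at 0.0313 against f/- but 0.58 with an estimated correlation, this cannot be told apart from an effect of Setdb1 with 2 f/- libraries, nor for either list from litters or library batches, which are not given.

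Of the 8 genes that differed between the control groups, Tmod4, Tsacc and Hist2h2bb lie within 10 Mb of Setdb1 on chromosome 3, starting at 95122799, 88282752 and 96269700 in GRCm38. That is 3 of 195 tested genes there and 5 of 11123 elsewhere (two-sided Fisher's exact p = 0.000265, with 0.00166 for 5 Mb and 0.000543 for 20 Mb). The genes' place prompted the test, and the 8 calls fell to 0 without f/+; Zp3-cre replicate 1 or 2, by limma (1584 at an unadjusted p below 0.05 with all libraries), so chance is left open; in mutants against f/+; Zp3-cre, where the same alleles differ, 14 of 195 and 538 of 11123 genes were called (Fisher's exact p = 0.131), and against f/- the p was 0.611. Hist2h2bb belongs to the histone list, which as a whole was lower in f/+; Zp3-cre than in f/- (mean log2 change -0.62). A level shared by that list in f/- and mutants is therefore 1 possible account of this gene. Sequence linked to the Setdb1 alleles, which f/- and mutant mice share, may also account for Hist2h2bb, whose mutant level of 10.3 ± 2.77 RPKM (n = 4) did not differ detectably from f/- (limma adjusted p = 0.943) and did from f/+; Zp3-cre (limma adjusted p = 9.8e-05). Linked sequence with the same effect in f/- and mutants does not account for Tmod4, at 0.242 ± 0.225 RPKM in mutants, which differed from f/- (limma adjusted p = 0.00080). The comparison cannot address a linked effect that changes with Cre or the loss of Setdb1, in which these groups also differ, and f/- has 2 libraries. Linked sequence is left open for Tsacc, at 23.4 ± 5.32 RPKM in mutants. Tsacc lay between the control groups and differed from f/- (limma adjusted p = 0.0473) and from f/+; Zp3-cre (limma adjusted p = 0.031).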
